A study of Mus musculus with 18 samples.

How the data were processed

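The series holds 18 mouse libraries in 6 groups of 3. Haematopoietic stem cells (HSCs) came from wild-type mice and from mice whose floxed Mettl3 gene had been deleted by Mx1-cre. Per the labels' protocols, mice of both genotypes received 5 injections of 10 µg pIpC, which induces Mx1-cre through interferon, and were analysed 10 days after the last. The sort took Lineage-negative, Sca1-positive, cKit-positive, CD150-positive, CD48-negative bone marrow cells, 3000 per sample. Polyadenylated RNA was incubated with 1.25 µg of an antibody against N6-methyladenosine (m6A). The washes were pooled as the unbound fraction, and bound RNA was released with free m6A nucleotide as the m6A-tagged fraction. Input, unbound and m6A-tagged RNA was amplified by Smart-seq2 and sequenced as paired 150-base reads, per the labels' protocols. No RNA fragmentation step is described there, so values are per gene and give no position of a methylated base. The series' design text calls the 3 samples of each group biological replicates.

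The authors deposited 2 tables, 1 per genotype, with 1 RPKM column (reads per kilobase of gene and per M reads, M being 1e6) for each fraction. Reads were placed on mm10, and Picard and edgeR were used in unstated roles and versions, per the submitters' processing notes. The aligner and the counting tool are not given in the sources used here. The values show that each of the 6 columns is the mean of 3 libraries, with 1 read added to every gene in every library. Both tables follow the same formula, with the same gene lengths, so columns were compared across them. A planned test across libraries assumed counts or a value per library. With 1 pooled RPKM column per group neither that test nor limma could be run, so no p-value is given. Reads of single libraries could be solved for low genes alone, 6 of which were among the genes compared.

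The depth of each library was worked out from the values. Of 23038 genes, 6986 had no read in any library, and their values give the gene lengths, 6972 of them within 0.005 bases of a whole number, and the sum of the 3 depth shares of each column. Genes with few reads then gave the separate shares. For 4218 genes the length came from a column without reads and reads were present elsewhere. The reads of the 3 libraries of a column were solved for these genes where exactly 1 solution existed. This held for 22618 of 23343 values tried (96.9%), and values with too many reads were not tried. The libraries are listed by depth, an order that is not the replicate number in the labels. On simulated tables of 23038 genes, 99.95% of 26429 solved values equalled the simulated reads. The simulation took the sum of the depth shares of each column as known.

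For each gene, log2((RPKM + 1)/(RPKM + 1)) was computed between columns, and the folds of named genes and lists are on this scale, which understates the change of genes with low values. The floor given for Cst7 is on reads per M reads. The ratios of H2-Q genes to H2-K1 and H2-D1 and the counts of lymphoid genes that differed 2-fold are on RPKM without an addition. The read added by the authors acts the same way. Genes with a mean of at least 10 RPKM over the 6 columns were compared, 6295 in all, and a gene counted as higher or lower at a 2-fold difference. These sizes were set once the unit was known, after an exploratory look that used the same 10 RPKM and the same added 1 RPKM. A genotype difference is the Mettl3-deficient log2 ratio minus the wild-type one. In simulated data for the Mettl3-deficient against wild-type input comparison of 6295 genes, with an assumed dispersion of 0.2, 92.0% of genes changed 4-fold and 100.0% of genes changed 8-fold passed 2-fold. Of unchanged genes, 5.53% passed. In the data 2.4% of genes were 2-fold higher and 6.7% lower in this comparison, so a 2-fold difference alone is weak for a single gene. The simulation gave every gene the same length and did not model reads that come mostly from 1 library, so its rates may differ from those of the data.

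Gene lists were fixed before the data were examined. The median log2 ratio of each list with at least 5 measured genes was placed among the medians of 10000 random lists of the same size matched on deciles of mean RPKM. This percentile describes these columns and is no test. Lists share members, so they are not separate results. Of the measured reported m6A targets, Cish, Egr1, Myc and Socs1 are also in the immediate early list, and Gata2, Kit and Tal1 in the HSC list. Of the lists fixed, lymphoid genes had 2 measured members, endothelial and stromal genes 4, and mitochondrially encoded genes 0, so they have no median. A further 8 lists were chosen after the values had been seen. They hold eosinophil granule, neutrophil granule, promyelocyte, classical MHC class I and H2-Q genes, and 3 lists with fewer than 5 measured members (B cell genes 3, globin and late erythroid genes 4, Y-linked genes 2), which have no median.

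The genes named in the text are the 10 highest and 10 lowest log2 ratios of each comparison (3 of each for unbound against input), skipping names that start with Gm and digits, end in Rik or hold -ps. From each list described, members come mainly from the 4 with the largest absolute log2 ratio. One such member is not reported here. Mettl3, Mettl14, Myc and reported m6A targets were also fixed. The planned rule asked for a p-value and for separation of replicates, which pooled columns cannot give. Other genes are named as values chosen after they were seen. Positions are from the GRCm38 (mm10) gene table, in which 22959 of the genes had an entry. Among the deposited gene names 25 had turned into dates and were matched by gene number, and 11 lines held no values. No column of per-sample values was left unused (0).

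Alternatives were scaling by median ratio or upper quartile, no minimum on RPKM, another way of choosing the m6A-enriched genes, an added 0.1 or 5 RPKM, and a minimum mean of 50 RPKM. The last 3 were chosen after seeing the data. The RPKM scaling sets each library to the same total, so a loss of m6A from all transcripts alike cannot be seen in any ratio of these columns. Intervals and floors given for reads cover counting error only, because amplified reads are not separate molecules. Reads of near-identical genes, such as the H2-Q genes, the Ear genes and ribosomal protein genes with processed copies, and reads of small nucleolar RNAs inside host genes, could have been split between copies or host by the counting, so these genes are uncertain. Scripts ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9.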

Results

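RNA of sorted HSCs was measured in 3 fractions, input, antibody-unbound and m6A-tagged, from wild-type and Mettl3-deficient mice, with 3 libraries per group. The study asked which transcripts of adult HSCs carry m6A that depends on Mettl3, the catalytic subunit of the m6A methyltransferase. Depth was 28.33 to 37.22 M reads (M, 1e6) per library in wild-type input, 24.3 to 27.38 M in wild-type unbound and 30.32 to 34.99 M in wild-type m6A-tagged RNA. In Mettl3-deficient cells it was 9.42 to 30.06 M in input, 12.24 to 27.27 M in unbound and 25.89 to 33.59 M in m6A-tagged RNA. Every RPKM below is the authors' mean of 3 libraries, and the differences between these means have no replicate check. The reads of single libraries could be solved for low genes, of which 6 were among the 6295 compared. Many of these low genes had reads from 1 library. They are the genes without a read in at least 1 of the 6 groups, which selects for patchy detection. Among those with a mean of 60 to 150 reads in a group, at least 90% of the reads came from a single library for 71.3% of genes in wild-type m6A-tagged RNA, 38.8% in wild-type unbound and 18.6% in wild-type input. The shares were 7.4%, 31.6% and 2.3% in the Mettl3-deficient fractions in the same order, against 0.0% from counting error alone. For 873 low genes with mean m6A-tagged and input reads summing to at least 20, wild-type libraries could be compared singly. All 3 m6A-tagged libraries lay above all 3 input libraries for 6 (0.7%) and below for 92 (10.5%). In Mettl3-deficient cells these were 59 (5.5%) and 30 (2.8%) of 1077, against 5% each for a random order without ties. A fraction with a library that had no reads cannot lie wholly above the other. Of low genes with a mean of 60 to 150 reads, 91.2% in wild-type m6A-tagged RNA and 35.9% in wild-type input lacked reads in at least 1 library. The 5% is therefore not the chance rate here, and no conclusion is drawn from these shares. Few of these genes are among those compared.

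Mettl3 itself (gene 56335, chromosome 14, 52294841 to 52308741) was present at 36.4 RPKM in wild-type and 19.6 RPKM in Mettl3-deficient input, 1.82-fold lower. It was also lower in the Mettl3-deficient unbound (33.2 against 11.2 RPKM) and m6A-tagged fraction (36.1 against 17.4 RPKM). Reads from exons outside the deleted part still count towards the gene, so the value checks the genotype labels in part. Mettl14, the partner of Mettl3 in the writer complex, was at 9.66 RPKM in wild-type and 6.19 RPKM in Mettl3-deficient input, and its mean lay under the minimum of 10 RPKM. Of the 8 measured writers, erasers and readers, Ythdf2, a reader that promotes decay of methylated transcripts, stood at 32.4 RPKM in wild-type and 66.7 RPKM in Mettl3-deficient input. The median of the list between the inputs was 0.03 on the log2 scale, at percentile 69.4 of random lists.

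In wild-type HSCs the m6A-tagged fraction held relatively more RNA of zinc finger proteins and short-lived transcripts than the input, and relatively less of ribosomal proteins. Pex11a (chromosome 7, 79735957 to 79743131), which acts in peroxisome division, was 4.73-fold higher, at 36.9 RPKM against 7.02 RPKM in input. Ccdc102a, B3galt4, Sertad1, Plekhf1, Nr0b2, Spsb2 and Elp6 were 3.16-fold to 4.29-fold higher, and Gata3, a transcription factor of T cells and HSCs, was 3.33-fold higher (29.8 against 8.26 RPKM). The lowest was Cenpv (chromosome 11, 62524944 to 62539869), 7.63-fold lower, followed by the proton pump subunit Atp6v1h, the retinol saturase Retsat and Lmo1, at 6.23-fold, 5.86-fold and 5.73-fold lower. Arl8a, Kctd13, Ccdc61, Rras, Ergic1 and Stk19 were 4.31-fold to 5.49-fold lower.

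Of 24 immediate early and short-lived transcripts, 21 lay above 0, with a median of 0.56 at percentile 100 of random lists. They included Gadd45g at 1.40 and Junb at 0.94. The 53 zinc finger protein genes had a median of 0.52 (percentile 100), with Zfp87 at 1.28 and Zfp956 at 1.27. The 27 HSC genes had a median of 0.38 (percentile 99.5), with 23 above 0, and the 19 granulocyte and monocyte genes one of 0.28 (percentile 99.2), with C1qb at 0.96. The reported m6A targets in blood cells had a median of 0.53 over 11 genes (percentile 98.8), among them Cish at 0.78, Gata2 at 0.61 and Myc at 0.56. Of 80 cytosolic ribosomal protein genes, 17 were 2-fold lower and 0 were 2-fold higher, and their median was -0.68 (percentile 0.0). Over all 6295 genes, 232 were 2-fold higher and 329 lower, so 41.4% of those differing were higher, a share of 30.5% under median-ratio and 21.5% under upper-quartile scaling.

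In Mettl3-deficient HSCs fewer genes stood apart in the same comparison, 86 of 6295 being 2-fold higher and 91 lower. The standard deviation of the log2 ratio across genes was 0.44, against 0.6 in wild-type cells. Of low genes with a mean of 60 to 150 m6A-tagged reads, 7.4% had at least 90% of them from 1 library, against 71.3% in wild-type cells. A noisier wild-type column was therefore not told apart from a difference in enrichment. The highest was Ybx3, a cold-shock RNA-binding protein, 6.48-fold higher in the m6A-tagged fraction (45.9 against 6.24 RPKM in input). It was followed by the selenoprotein gene Selenon (6.44-fold), the transcription factor Cebpb (5.55-fold), Arf6 (4.80-fold), the corepressor gene Rcor1 (4.19-fold), Sox4 (4.10-fold), Lrg1 (3.66-fold), Cited2 (3.17-fold), Suds3 (3.15-fold) and Dapk3 (3.03-fold). Their wild-type input was higher than their Mettl3-deficient input in each case, for Ybx3 218 RPKM and for Selenon 39.2 against 2.91 RPKM. The lowest were Snord95, a small nucleolar RNA inside the Rack1 gene, 10.2-fold lower, and the ribosomal protein genes Rps16, Rps23, Rps29, Rpl11 and Rpl23, 3.66-fold to 6.72-fold lower. The MHC class I genes H2-Q2, H2-Q1 and H2-Q4 were 6.47-fold, 4.42-fold and 3.91-fold lower.

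Cst7, a protease inhibitor of cytotoxic and myeloid cells, had 79, 183 and 12 reads in the 3 Mettl3-deficient input libraries and 0 reads in each m6A-tagged library, so it was at least 133.6-fold lower there against a floor of 3 reads over the group. Immediate early transcripts again stood high, with a median of 0.61 (percentile 100), 7 of 24 being 2-fold higher, among them Cebpb at 2.47, Egr1 at 1.57 and Socs1 at 1.29. The list of replication-dependent histone genes, which also took in the linker histones H1f0 and H1f10 made outside S phase, had a median of 0.48 over 9 genes (percentile 97.7), with H1f10 at 1.43. Ribosomal protein genes had a median of -0.97 (percentile 0.0), with 36 of 80 at least 2-fold lower. MYC targets, mostly genes of ribosome production, had a median of -0.18 over 44 genes (percentile 0.03), with Ldha at -1.13 and Npm1 at -1.02. The median of HSC genes was 0.07 (percentile 40). Of all genes differing 2-fold, 48.6% were higher, a share of 28.2% under median-ratio and 28.5% under upper-quartile scaling.

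The genotype difference in m6A-tagged against input asked which enrichments differed in Mettl3-deficient cells. Of the 10 genes lowest in Mettl3-deficient relative to wild-type cells 6 were H2-Q genes, H2-Q2 by 6.58-fold, H2-Q1 by 6.33-fold, H2-Q4 by 4.42-fold, H2-Q6 by 4.11-fold, H2-Q8 by 3.98-fold and H2-Q9 by 3.75-fold. These genes were also higher in Mettl3-deficient input, for H2-Q9 924 against 91.3 RPKM. Their Mettl3-deficient unbound values lay under input as well. H2-Q1 had 198, 46.5 and 44.1 RPKM in Mettl3-deficient input, unbound and m6A-tagged RNA, and H2-Q4 79.9, 21.7 and 19.7 RPKM. The Mettl3-deficient input column thus stood apart from both other fractions. H2-Q2 was near the floor in wild-type cells, at 0.28 RPKM in input and 0.303 RPKM in m6A-tagged RNA. Cst7, without reads in the Mettl3-deficient m6A-tagged libraries, ranked between H2-Q1 and H2-Q4. Ranked next after H2-Q4, Snord95 was lower by 4.26-fold, Snord37, which lies inside the elongation factor gene Eef2, by 4.23-fold, and Rpl11 by 4.12-fold. Highest were Ybx3 by 9.16-fold, Retsat by 8.77-fold, the chromosome condensation regulator Rcc2 by 7.69-fold and Cenpv by 6.70-fold. Stk19, Ankrd13d, Ccdc61, Pomgnt1, Selenon and Mpnd followed, by 5.16-fold to 6.50-fold.

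HSC genes had a median genotype difference of -0.29 (percentile 0.60), with 19 of 27 below 0, among them Slamf1, which encodes the CD150 used in the sort, at -0.96, Angpt1 at -0.93 and Meis1 at -0.92. Zinc finger protein genes had a median of -0.22 (percentile 2.03), MYC targets -0.19 (percentile 0.24) and ribosomal protein genes -0.30 (percentile 0.0). Reported m6A targets had a median of -0.08 (percentile 28.9), with Myc at -0.08, Gata2 at -0.54 and Socs1 at 0.99. Over all genes 460 were 2-fold higher and 183 lower in Mettl3-deficient relative to wild-type cells.

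Of the 232 genes 2-fold higher in the wild-type m6A-tagged fraction, 66 (28.4%) had an enrichment at least 2-fold lower in Mettl3-deficient cells. Of the genes compared, these 66 of 6295 became 1.84% without a minimum on RPKM, 0.48% with an added 5 RPKM and 0.25% with a minimum mean of 50 RPKM. Besides Snord37 they were led by Pex11a, whose log2 ratio was 2.24 in wild-type and 0.39 in Mettl3-deficient cells, and by Elp6 (1.66 and 0.02), Gata3 (1.73 and 0.12), Ccdc102a (2.10 and 0.48), Ctla2b (1.34 and -0.21), Orc5 (1.06 and -0.43) and Rtp4 (1.60 and 0.17). The mirror-image selection gave a larger share, 33 of the 86 genes enriched in Mettl3-deficient cells (38.4%) being at least 2-fold lower in wild-type cells. Genes chosen for a high value in either genotype therefore lay lower in the other, with medians of 0.41 and 0.42 against 1.12 and 1.15 where they were chosen. Of the wild-type 2-fold genes 88.4% still lay above 0 in Mettl3-deficient cells, against 61.5% of all genes. Across genes, which are not independent replicates, the log2 ratios of the genotypes had a Pearson correlation of 0.32 and a Spearman correlation of 0.32. Both ratios were 2-fold higher for 11 genes (3.2 for independent lists) and 2-fold lower for 20 (4.8).

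Set against the unbound fraction, the wild-type m6A-tagged RNA stood much further apart, with 1982 genes 2-fold higher and 1218 lower. Nup62 (chromosome 7, 44816088 to 44831836), a nuclear pore protein, was 83.5-fold higher, at 111 against 0.341 RPKM. The ribosome assembly factor Grwd1 was 56.5-fold, Sertad1 50.1-fold, Tmem251 43.5-fold, the mitochondrial rRNA methyltransferase Mrm3 41.1-fold and the AP-1 subunit Jun 36.1-fold higher. Gna15, Gypc, Rpp38 and Taf5l were 35-fold to 37.5-fold higher. The size of these folds rests on the added RPKM, 8 of the 20 named genes moving over 1.5-fold with an added 0.1 RPKM and 16 with an added 5 RPKM. Lmo1 was 15.6-fold, Ccdc61 11.3-fold and Atp6v1h 10.5-fold lower, and Immp2l, Retsat, Cenpv, Kctd13, Chchd6, Ergic1 and Tmem101 were 8.38-fold to 9.71-fold lower. Myc (chromosome 15, 61985341 to 61990361) stood at 117 RPKM in input, 5.82 RPKM in unbound and 174 RPKM in m6A-tagged RNA, 25.6-fold higher in the last than in unbound.

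Of the lists, immediate early transcripts had a median of 2.41 (percentile 100), 21 of 24 being 2-fold higher, and the 11 reported m6A targets one of 2.5 (percentile 99.9), 8 being 2-fold higher, with Egr1 at 3.59, Mdm2 at 2.98 and Tal1 at 2.97. Zinc finger protein genes had a median of 2.11 (percentile 100), with 36 of 53 at least 2-fold higher, led by Zfp24 at 4.94. The m6A regulators themselves had a median of 2.26 over 8 genes (percentile 99.6), with the readers Ythdf2 at 3.90, Ythdf3 at 3.57 and Ythdf1 at 2.93. HSC genes had a median of 1.23 (percentile 99.9), with Erg at 4.26, Mycn at 3.60 and Slamf1 at 3.34. Megakaryocyte genes had one of 1.09 over 13 genes (percentile 99.1), with Mmrn1 at 5.11. Ribosomal protein genes had a median of -1.58 and nuclear oxidative phosphorylation genes one of -0.99 (percentiles 0.0 and 0.04), with 70 of 80 and 46 of 94 genes at least 2-fold lower. Of genes differing 2-fold 61.9% were higher, a share of 56.3% under median-ratio and 47.2% under upper-quartile scaling. Upper-quartile scaling moved the median of all genes from 0.12 to -0.23.

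**Figure D1:**
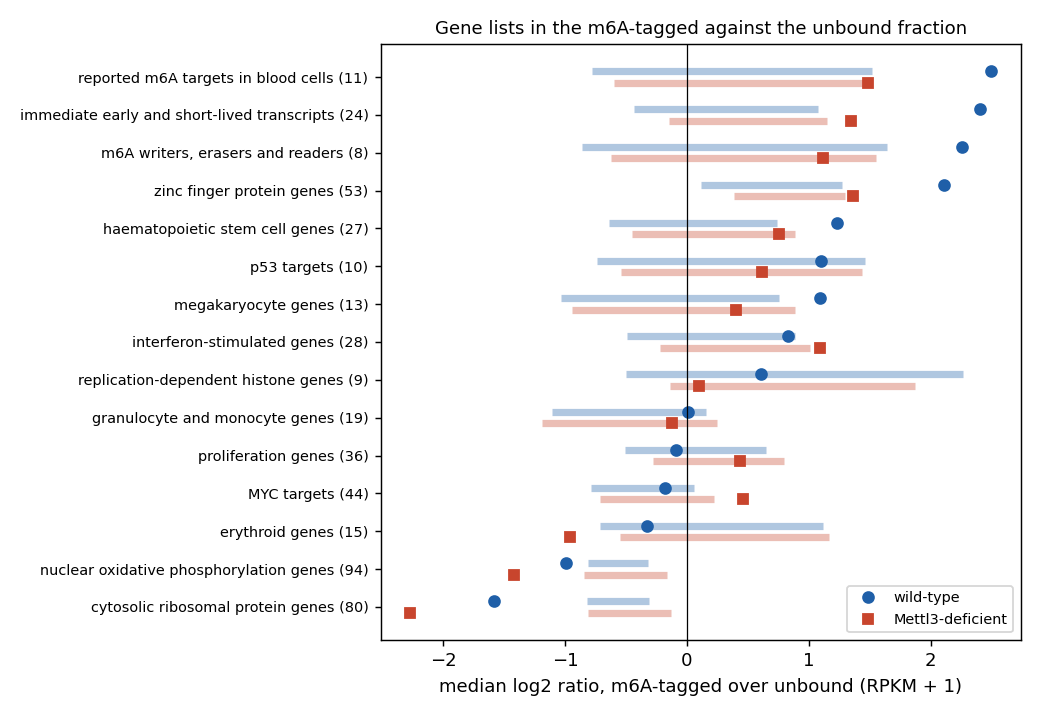
Median log2 ratio of m6A-tagged over unbound RNA (RPKM + 1) for each gene list, with the number of measured genes, in wild-type (circles) and Mettl3-deficient cells (squares). Bars span the central 95% of 10000 random lists matched on mean RPKM. Ribosomal protein genes lie lowest in both genotypes, at -1.58 and -2.27, and reported m6A targets highest, at 2.5 and 1.49.

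In Mettl3-deficient cells the m6A-tagged fraction also differed from the unbound fraction for many genes, 2122 being 2-fold higher and 1061 lower. Taok3 (chromosome 5, 117120111 to 117275101), a protein kinase, was 25.0-fold higher, Mat2a, which makes the methyl donor S-adenosylmethionine, 23.8-fold, the interferon-induced GTPase gene Gbp7 23.0-fold and the integrin-binding protein gene Tln1 21.2-fold. Rbm28, Secisbp2, Timeless, Mc5r, Srrm2 and Leng8 were 19.7-fold to 20.9-fold higher. Of the 20 named ratios 11 moved over 1.5-fold with an added 5 RPKM and 5 with an added 0.1 RPKM. The lowest were mostly ribosomal protein genes, Rps16 by 17.6-fold, Rps29 by 14.2-fold, Rplp2 by 12.6-fold and Rps23, Rps21, Rps13 and Rps28 by 10.7-fold to 11.3-fold. Snord95 (16.4-fold), the ATP synthase subunit Atp5md (14-fold) and Tm2d1 (12.3-fold) were lower too. Myc was 2.82-fold higher in m6A-tagged than in unbound RNA.

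Longer genes lay higher in this comparison. Over 5 groups of genes of rising genomic span, the median log2 ratio went from -0.54 to 1.26 in Mettl3-deficient cells and from -0.15 to 0.39 in wild-type cells. The Spearman correlation with span across 6287 genes was 0.41 in Mettl3-deficient and 0.09 in wild-type cells. Immediate early transcripts had a median of 1.35 (percentile 99.4), reported m6A targets 1.49 (97.9), interferon-stimulated genes 1.09 (98.7), zinc finger protein genes 1.36 (98.8) and MYC targets 0.46 (99.8). Interferon-stimulated genes were led by Stat2 at 3.97, and with a minimum of 50 RPKM their median lay under that of random lists, by -0.06. Ribosomal protein genes had a median of -2.27, oxidative phosphorylation genes -1.42 and erythroid genes -0.96 (percentiles 0.0, 0.0 and 0.14). Of genes differing 2-fold 66.7% were higher, a share of 54.6% under median-ratio and 49.7% under upper-quartile scaling, which moved the median of all genes from 0.33 to 0.05 and -0.07.

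**Figure D2:**
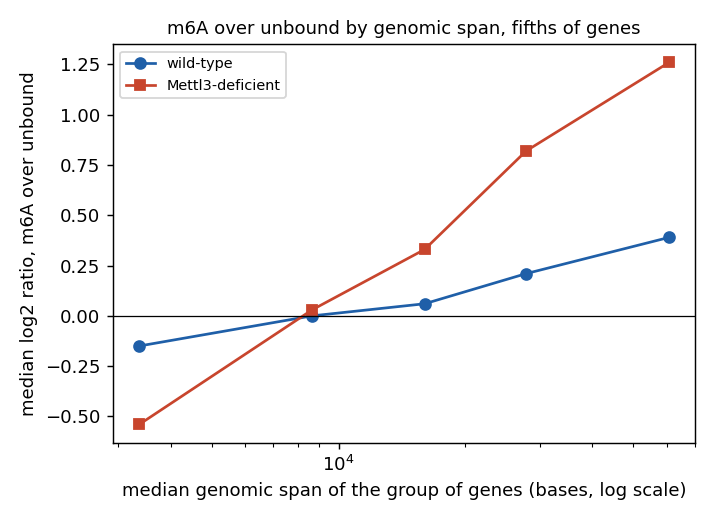
Median log2 ratio of m6A-tagged over unbound RNA (RPKM + 1) in 5 groups of genes of equal size against the median genomic span of each group in bases (log axis), for wild-type (circles) and Mettl3-deficient cells (squares). The median runs from -0.54 at 3368 bases to 1.26 at 60768 bases in Mettl3-deficient and from -0.15 to 0.39 in wild-type cells.

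Between genotypes, the m6A-tagged against unbound ratio of short-lived transcripts, zinc finger protein, ribosomal protein and oxidative phosphorylation genes was lower in Mettl3-deficient cells, and that of proliferation genes and MYC targets was higher. Tmem251 (chromosome 12, 102743719 to 102745406) was lower by 53.6-fold, the mitochondrial transcription factor Tefm by 34.3-fold, the ribonuclease P subunit Rpp38 by 32.4-fold, Grwd1 by 31.5-fold and the interferon-induced Rtp4 by 30.5-fold. Mrm3, the mRNA export factor Nxt1, Ccnq, Mfsd5 and Tpst2 were lower by 22.1-fold to 25.8-fold. In each case the unbound column was the one that differed most, Tmem251 having 0.372 RPKM in wild-type and 46.6 RPKM in Mettl3-deficient unbound RNA. Arfgap3 was higher by 25.1-fold, the decapping scaffold Edc4 by 18.9-fold, Anks3 by 18.5-fold, Carmil2 by 17.6-fold and the ATP citrate lyase Acly by 17.3-fold. Atxn2l, Snx9, Retsat, Iars and Stat5a were higher by 13.7-fold to 14.9-fold. Of these 20 ratios 15 moved over 1.5-fold with an added 5 RPKM and 6 with an added 0.1 RPKM.

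Myc was lower by 9.10-fold, its unbound value being 5.82 RPKM in wild-type and 48.0 RPKM in Mettl3-deficient cells. Reported m6A targets had a median of -1.12 (percentile 1.43), 6 of 11 being 2-fold lower and 3 higher, with Gata2 at -1.96, Kit at 3.02 and Mybl2 at 2.02. Immediate early transcripts had a median of -0.90 (percentile 0.54), with 11 of 24 at least 2-fold lower, and zinc finger protein genes one of -0.62 (percentile 0.74). Ribosomal protein genes had a median of -0.82 and oxidative phosphorylation genes -0.62 (percentile 0.0 for both). Proliferation genes had a median of 0.93 (percentile 99.9), 17 of 36 being 2-fold higher, among them Hells at 2.15, Mcm2 at 2.14 and Top2a at 2.12. MYC targets had one of 0.68 (percentile 99.9), with Mybbp1a at 3.41 and Cad at 2.87 but Grwd1 at -4.98. Over all genes 1493 were 2-fold higher and 1435 lower, and median-ratio scaling moved the median from -0.01 to -0.16. The genotypes' m6A-tagged against unbound ratios had a Pearson correlation of 0.56 across genes, with 1156 genes 2-fold higher in both (668.1 for independent lists).

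The unbound fraction against input showed which transcripts stayed in the washes, where ribosomal protein and oxidative phosphorylation genes stood high in both genotypes. In wild-type cells Nup62 was 46.8-fold, Grwd1 28.9-fold and Csgalnact1 26.9-fold lower in unbound RNA, and the chemokine Ccl5 was 3.44-fold, the 45S ribosomal RNA precursor Rn45s 3.17-fold and Rab26os 3.08-fold higher. In Mettl3-deficient cells Mat2a was 30-fold, Taok3 26.6-fold and Gbp7 24.6-fold lower, and the proteasome assembly factor Psmg4 was 7.34-fold, Hspb11 7-fold and Tm2d1 5.79-fold higher. Ribosomal protein genes had medians of 0.90 and 1.35 in wild-type and Mettl3-deficient cells, and oxidative phosphorylation genes 0.85 and 1.51 (percentile 100 in all 4). Zinc finger protein genes had medians of -1.54 and -1.12 (percentiles 0.0 and 1.99), the second of which lay above random lists, by 0.05, with a minimum of 50 RPKM. In wild-type cells 290 genes were 2-fold higher and 1604 lower, 15.3% of them higher, a share of 22.0% under median-ratio and 39.8% under upper-quartile scaling. In Mettl3-deficient cells 1162 were higher and 1854 lower, 38.5% higher, with shares of 46.1% and 51.9%. Upper-quartile scaling moved the medians of all genes from -0.05 to 0.19 and from -0.13 to 0.15.

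The inputs of both genotypes show transcript levels of HSCs 10 days after the last pIpC dose. Granule genes of eosinophils and neutrophils were far lower in Mettl3-deficient cells, and MHC class I and interferon-stimulated genes were higher. The eosinophil granule protein genes Prg2 (chromosome 2, 84980461 to 84983632), Epx and Prg3 were 101-fold, 50.3-fold and 32.0-fold lower, Prg2 having 655 RPKM in wild-type and 5.52 RPKM in Mettl3-deficient input. Retnlg was 36.9-fold, Ybx3 30.2-fold, Wfdc21 27.5-fold, the neutrophil collagenase gene Mmp8 25.1-fold and Lrg1 20.5-fold lower, and the eosinophil ribonuclease genes Ear2 and Ear6 25.4-fold and 20.5-fold. H2-Q2 (chromosome 17, 35342307 to 35346764) was 48.0-fold higher, at 0.28 against 60.4 RPKM, and H2-Q4, H2-Q9, H2-Q8, H2-Q7 and H2-Q5 were 6.39-fold to 18.8-fold higher. Ccn3 was 20.3-fold and Serpina3f 7.21-fold higher. Rn45s was 27.2-fold higher (15.5 against 448 RPKM) and Lars2, a mitochondrial leucyl-tRNA synthetase, 21.2-fold. Both were also higher in Mettl3-deficient unbound RNA (Rn45s 51.3 against 1150 RPKM, Lars2 2.52 against 317 RPKM). The same held in m6A-tagged RNA (8.0 against 185 and 6.7 against 150 RPKM). Whether these values are transcript levels of HSCs or ribosomal RNA left among the polyadenylated RNA was not tested. Folds over values near 1 RPKM, such as 0.273 RPKM for Epx, rest on the added RPKM, and 13 of the 20 named ratios moved over 1.5-fold with an added 5 RPKM and 8 with an added 0.1 RPKM.

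Of 19 granulocyte and monocyte genes 14 were 2-fold lower and 0 higher, with a median of -2.90 (percentile 0.0). Elane, a protease of promyelocytes, was at -3.97, Fcnb at -3.82, Ctsg at -3.69 and Ly6c2 at -3.68, while Csf3r was at -0.05 and Spi1 at 0.33. Erythroid genes had a median of -0.92 (percentile 0.0), 7 of 15 being 2-fold lower, among them the carbonic anhydrase Car1 at -3.05 and Klf1 at -2.56. Megakaryocyte genes had a median of -0.34 (percentile 2.42), with Mmrn1 at -3.17 and Pf4 at -2.41. Histone genes had a median of -1 (percentile 0.07), with H1f10 at -3.28 and H2ac23 at -3.00, and oxidative phosphorylation genes one of -0.13 (percentile 0.56). Proliferation genes lay at the edge of random lists, with a median of -0.22 (percentile 2.51) and E2f1 at -1.38. Interferon-stimulated genes had a median of 0.63 (percentile 100), 9 of 28 being 2-fold higher and 0 lower, with Cxcl10 at 2.39, Oasl1 at 2.01 and Irf7 at 1.35. HSC genes had a median of -0.04 (percentile 51.2), with Ly6a at 1.55 and Sult1a1 at -1.86, and MYC targets 0.09 (percentile 89.8). The medians of ribosomal protein genes, 0.07 (percentile 80.9), and p53 targets, 0.18 (percentile 90.7), lay within the central 95% of random lists. Over all genes 150 were 2-fold higher and 420 lower.

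**Figure D3:**
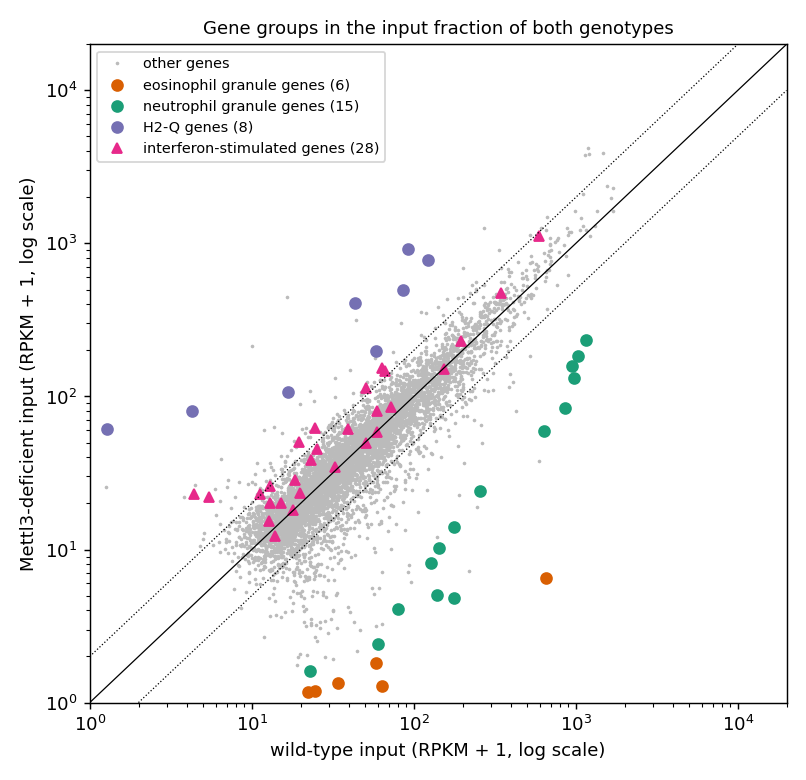
Input RPKM + 1 of wild-type (x axis) against Mettl3-deficient cells (y axis), both log scaled, for the 6295 genes compared, with 4 gene groups in colour, the line of equality and dotted lines at 2-fold. All 15 neutrophil and 6 eosinophil granule genes lie under the lower dotted line and all 8 H2-Q genes above the upper one.

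Transcripts enriched by the antibody in wild-type cells were somewhat higher in Mettl3-deficient input than matched genes. The 1982 genes 2-fold higher in m6A-tagged than in unbound RNA, a choice that uses no input library, had a median log2 ratio of 0.118 between the inputs. Random lists had a median of -0.161 (central 95%, -0.185 to -0.134), and the other genes one of -0.115. Of the set, 81 genes were 2-fold higher and 94 lower. The excess over random lists, 0.28, was 0.10 without a minimum on RPKM. Chosen instead on m6A-tagged against input, a choice that shares the wild-type input with the comparison, 232 genes had a median of 0.303.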

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

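The alternatives with an added 0.1 or 5 RPKM and with a minimum mean of 50 RPKM were chosen after seeing the data, and the others before the data were examined. Under median-ratio and upper-quartile scaling and with an added 0.1 RPKM, the shares of genes differing 2-fold and the other main results stayed within 1.5 times of their value or 0.1 of a correlation (14 of 14 each). How those genes split into higher and lower moved further with scaling, the share higher in m6A-tagged against input going from 41.4% to 21.5% in wild-type cells (upper quartile) and from 48.6% to 28.2% in Mettl3-deficient cells (median ratio). In unbound against input of wild-type cells it went from 15.3% to 39.8% (upper quartile). Gene list medians, taken against random lists, were near their first value in 756 of 783 recomputations, moved in 24 and changed direction in 3. Among genes named by rank, none of 815 recomputed ratios changed direction, but 79 of 152 moved over 1.5-fold with an added 5 RPKM and 34 of 152 with an added 0.1 RPKM. By number, most of these belonged to m6A-tagged against unbound, its genotype difference and the inputs. Of the 6 genes named for unbound against input in wild-type cells, 3 moved with either added value. Below, values are percentages of the genes compared that differed 2-fold unless another measure is named, and the cause was not tested except that more low genes enter without a minimum and that a larger added value shrinks their ratios.

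Without a minimum on RPKM, the share was 1.82% in place of 2.81% for m6A-tagged against input in Mettl3-deficient cells. For m6A-tagged against unbound it was 29.9% in place of 50.8% in wild-type and 27.6% in place of 50.6% in Mettl3-deficient cells, and 23.8% in place of 46.5% for the genotype difference. For unbound against input in Mettl3-deficient cells it was 25.1% in place of 47.9%. Genes enriched in wild-type cells and at least 2-fold less so in Mettl3-deficient cells (66 of the 6295 before) were 1.84%, and the correlation of m6A-tagged against input ratios between genotypes was 0.19 in place of 0.32. The excess of the wild-type m6A-enriched set over random lists in the inputs, 0.28 on the log2 scale, became 0.10. Chosen on m6A-tagged against input, the set's excess was 0.39.

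With an added 5 RPKM, m6A-tagged against input gave 5.19% in place of 8.91% in wild-type, 1.59% in Mettl3-deficient cells and 6.69% in place of 10.2% for the genotype difference. Genes less enriched in Mettl3-deficient cells were 0.48% and the excess in the inputs 0.23. With a minimum mean of 50 RPKM, unbound against input in wild-type cells gave 18.5% in place of 30.1%, genes less enriched in Mettl3-deficient cells 0.25% and the excess in the inputs 0.41. With that minimum the interferon-stimulated genes in Mettl3-deficient cells lay at -0.06 against random lists in m6A-tagged against unbound (0.74 before) and at 0.12 in unbound against input (-0.81 before), and zinc finger protein genes at 0.05 in the latter (-0.51 before).

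No paired analysis was possible because the columns are pooled and carry no replicate numbers. For the same reason, leaving out single replicates, the replicate block, count tests, voom, a stricter adjusted p, a test against a minimum fold, a filter on the number of libraries, a fit to the compared groups alone and set tests with an estimated correlation were not run. Scaling to library size alone is what RPKM already is. Depth limits low genes most in Mettl3-deficient unbound RNA, with 53.43 M reads over its 3 libraries.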

Other observations

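Most tests in this part were chosen after the result was seen. Only the test of the region around the H2-Q genes and the tests of gene span on m6A-tagged against unbound RNA (0.41 and 0.34) were written before their results were seen. The eosinophil, neutrophil, promyelocyte, MHC class I and H2-Q lists and the single genes named here were chosen after their values were seen.

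Genes of the classical MHC class I pathway were higher in Mettl3-deficient input, with a median of 1.03 over 8 genes (percentile 100), of which 3 are also in the interferon-stimulated list. H2-K1 was at 1140 RPKM in wild-type and 3770 RPKM in Mettl3-deficient input, H2-D1 at 1190 and 4190 RPKM, and B2m, the shared light chain, at 1480 and 3890 RPKM. Of the 8 genes 0 were 2-fold higher in all fractions, H2-K1 being at 1410 and 2060 RPKM and B2m at 1750 and 2130 RPKM in m6A-tagged RNA. Actb was at 1200 and 3830 RPKM. Granule genes were lower. The 15 neutrophil granule genes, 7 of them also in the granulocyte and monocyte list, had a median of -3.65, and the 6 eosinophil granule genes one of -4.83. The 5 promyelocyte genes, all in that list too, had a median of -3.47, with Prtn3 at -0.63. B cell genes went both ways. The 3 measured ones were not lower, Cd74 being at 337 RPKM in wild-type and 902 RPKM in Mettl3-deficient input, H2-Aa at 152 and 205 RPKM and Cd79b at 84.7 and 90.6 RPKM. Vpreb1 and Cd79a, under the minimum, were at 11.6 and 5.21 RPKM in wild-type and 1.95 and 0.252 RPKM in Mettl3-deficient input, Cd3d at 14.4 and 1.12 RPKM, and Nkg7, of cytotoxic cells, at 188 and 46.2 RPKM.

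The Y-linked genes Ddx3y and Eif2s3y were at 14.5 and 45.8 RPKM in wild-type and 15.6 and 47.6 RPKM in Mettl3-deficient input, while Xist, expressed from the inactive X chromosome, was at 3.27 and 0.122 RPKM. Some low transcripts came from 1 library. Acta2 had 135, 0 and 0 reads and Ms4a1 155, 0 and 0 reads in the wild-type input libraries. In the authors' deposited table, Cst7 and Chchd2 carry a note of significance in eluted RNA against input and not in flow-through against input, and Rps14 a note of opposite directions. Chchd2 was at 208, 387 and 117 RPKM in wild-type input, unbound and m6A-tagged RNA and at 284, 750 and 92.2 RPKM in the Mettl3-deficient fractions. Rps14 was at 1070, 2060 and 411 RPKM and at 1220, 3930 and 433 RPKM.

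Granulocyte genes were lower in Mettl3-deficient input by a median of -2.90. Uneven amplification of the input libraries alone is argued against, because the same 19 genes had medians of -2.63 in unbound and -2.68 in m6A-tagged RNA, each amplified separately. A smaller share of mature blood cells of several kinds in the Mettl3-deficient sort may account for the pattern. Of 15 lymphoid genes at 1 RPKM or more in an input, 10 were 2-fold lower (66.7%, exact 95% binomial interval 38.4% to 88.2%) and 1 higher. Of all genes compared 6.7% were 2-fold lower, which is not a like baseline. That share is on RPKM + 1 for genes with a mean of at least 10 RPKM. Most of the lymphoid genes lay under that minimum and were called on RPKM without an addition. The medians of erythroid and megakaryocyte genes were lower too. These values leave the explanation open. The lineage gate of the sort is meant to remove mature cells, yet wild-type input held granule transcripts such as S100a8 at 1150 RPKM and Prg2 at 655 RPKM. Lower expression within HSCs of the Mettl3-deficient genotype was not tested and also stays open, since the cells of each genotype were sorted apart.

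H2-Q genes were higher in Mettl3-deficient input, by a median of 2.95 with all 8 measured members 2-fold higher, though 5 of 8 were so in all fractions and H2-Q1 was lower in unbound (52.7 against 46.5 RPKM) and m6A-tagged RNA (83.2 against 44.1 RPKM). A difference between the mice over the whole surrounding region of chromosome 17 could be seen here only through expression. Of 206 other genes within 5 Mb, 21 differed 2-fold (10.2%, exact 95% binomial interval 6.4% to 15.2%, against 9.1% of all genes). This share was set beforehand to argue against it. However, H2-Q8 and H2-Q9 are listed at 1642938 and 1714853, far from the other members, so the region may take in unrelated genes. A difference in sequence that left the expression of neighbours unchanged stays open. Reads shared with H2-K1 and H2-D1 stay open, because the ratio of the H2-Q genes to the sum of those genes was higher in Mettl3-deficient cells by a median of 2.38-fold in input and 4.55-fold in unbound but 1.5-fold in m6A-tagged RNA. In input the ratio ranged from 1.01-fold for H2-Q1 to 63.2-fold for H2-Q2, which was near the floor in wild-type cells. A variant limited to the H2 genes (the labels name 1 strain for both genotypes), a stronger interferon response and the Mettl3 genotype itself were not tested apart and stay open.

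Longer genes were higher in m6A-tagged against unbound RNA, with a rank correlation with genomic span of 0.41 in Mettl3-deficient cells (95% bootstrap interval over genes 0.39 to 0.43) and 0.09 in wild-type cells (0.07 to 0.11). Against input, unbound RNA had correlations of -0.20 in wild-type and -0.47 in Mettl3-deficient cells and m6A-tagged RNA -0.11 and -0.17, so the trend lies in the unbound columns. A rule set beforehand for long RNA held by the antibody step without Mettl3 was met. It asked for a positive correlation in Mettl3-deficient cells that was not clearly under the wild-type one. It does not tell whether the RNA was released, and the outcome was left undecided. The narrower case, RNA of long-span genes held and then released, was tested after this result was seen and is argued against. Such RNA would be higher in m6A-tagged RNA than in input, where the correlation was -0.17 (-0.19 to -0.14). Genomic span includes introns and RNA length was not measured, so no verdict is drawn on long RNA as such. RNA held and not released stays open. Loss of Mettl3-dependent binding from long-span genes was not seen in these pooled columns, but no verdict is drawn on it. The correlation of the genotype difference with span, 0.34 (0.31 to 0.36), was set beforehand to argue against it when above 0. Against input, where lost binding would give a value below 0, it was 0.02 (-0.0 to 0.04). Lost binding would also raise unbound RNA of such genes, yet its correlation was lower in Mettl3-deficient cells (-0.47 against -0.20). The values 0.34 and -0.47 both rest on the unbound columns. Another source of the trend in those columns could still mask a loss there, so the explanation stays open. Residual m6A and differences in RNA integrity between the unbound samples were not tested.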
